A study of Homo sapiens with 30 samples.

How the data were processed

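RNA was sequenced from 30 libraries of 2 human prostate cancer cell lines, LAPC4 and LNCaP, both derived from lymph node metastases. They fell into 10 groups of 3, given by the cell line, the line (parental or palbociclib-resistant) and the treatment. The series text calls the replicates biological, while the labels do not say whether they were separate cultures, so the p-values measure only the spread between these samples.

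The deposited tables hold counts, whole-number reads per gene symbol for each library, with no normalization applied. Beside them, per the file headers, each of the 12 tables holds the authors' log2 fold change between a pair of groups. Per the file headers, they also hold the authors' p-value and its adjusted form. Per the submitters' processing notes, HTSeq and DESeq2 were used with genome build hg19, without versions or the role of each tool. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. Counts of a gene that overlaps another on the opposite strand, or that belongs to a family of similar sequences, are therefore less certain. Among the genes named below this applies at least to EMC3-AS1, LOC100506123 and MAGEA4. The tables give no coordinates, so genes are identified by symbol and Entrez GeneID.

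Each table had 25375 gene entries, of which 6 exact duplicates were removed, leaving 25369 genes, 514 of them without an Entrez identifier. A library that recurs in several tables had identical counts each time (42 repeated columns), and 2534 genes were at 0 in every library. Library totals lay between 40.2 and 54.4 M (mega) counts, genes with at least 1 count between 17377 and 18656, and the share of the 10 most abundant genes between 3.29% and 6.01%.

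Each cell line was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (15515 tested in LAPC4 and 16070 in LNCaP) and libraries scaled by the trimmed mean of M values, with factors between 0.940 and 1.07. The quasi-likelihood test was run on a model with 1 mean per group, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The biological coefficient of variation was 0.0897 in LAPC4 and 0.112 in LNCaP, with 8 and 12 residual degrees of freedom per gene and a prior of 7.84 and 7.98. Standard errors of log2 fold changes were derived from the F statistic. Normalized counts are counts scaled to the mean library and given as mean ± SD of 3 libraries. Intervals and lower bounds for genes at or near 0 cover counting error only. They take 3 counts over the group as the floor for a group at 0, and 95% as the confidence level.

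There were 12 comparisons of a pair of groups and 3 interaction tests, in which the palbociclib response of a resistant line was set against that of its parental line. For each comparison a rule names genes. It takes the 6 largest positive and 6 largest negative log2 fold changes among genes past 0.05 with a mean normalized count of at least 100. It adds a panel of genes of the cell cycle and of signalling (among them RB1, CDK4, CDK6, CDK2, CCND1, CCNE1, CCNE2, CDKN1A, CDKN2A, E2F1, MKI67, KLK3 and DUSP6). It also adds up to 4 members with the smallest adjusted p and a mean of at least 20 in each list described. From these the text gives a selection, made without a fixed rule, in which cell cycle genes are prominent. In all 4 genes and 1 of the gene lists were analysed and are not reported here.

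The 20 gene lists held 598 entries, of which 594 matched a gene in the tables. They include E2F and S-phase genes, G2 and mitosis, the RB and CDK core, luminal epithelial, basal and stem, mesenchymal and neuroendocrine genes. Further lists cover p53 targets, ATF4 and the unfolded protein response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, ribosome biogenesis, lysosome, and MAPK output. Others cover receptor tyrosine kinases and ligands, the senescence-associated secretory phenotype, interferon and MHC genes, leukocyte markers and fibroblast or endothelial markers. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 20 lists of a comparison. A correlation of 0.05, ranks and an estimated correlation were alternatives, together with fry. The estimated-correlation test and fry were run on unweighted log2 counts-per-million (prior count 2). With voom's weights the estimated p depended on the order of the groups in the design, by up to 25.7-fold, and this change was made after that dependence was found.

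The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 (with and without its independent filtering), DESeq2's size factors, no filter on low counts, fits of only the compared libraries, and a replicate block. Others were a threshold of 0.01, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Added after seeing the data were a fit without 2 LNCaP libraries whose profiles did not match their labels, offsets for GC content and gene length, the authors' deposited adjusted p, and a fit of all 30 libraries. GC content and length came from GENCODE gene models and were found for 92.4% of tested genes in LAPC4 and 92.0% in LNCaP. In single libraries they explained 0.27% to 11.3% of the variance in LAPC4 and 0.156% to 7.53% in LNCaP. For LNCaP comparisons that hold the 2 libraries, the number of genes and the named lists and part of the named genes are also given from the fit without them.

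The procedure was tested on simulated data with 50 changed genes per fold. In the comparison of LAPC4 parental palbociclib and vehicle, 28% of genes changed 1.25-fold were recovered, 68% at 1.5-fold, 72% at 2-fold and 96% at 4-fold. Of 158 calls there, 11 (6.96%) were false. For LNCaP parental cells the recovery was 14%, 74%, 82% and 94%, and 8 of 151 calls (5.30%) were false. A simulated fall of the E2F list was called in both (camera adjusted p = 3.12e-54 and 8.08e-35), with 0 other lists called. The simulated genes were drawn independently of one another, while members of a real list can vary together. The simulation therefore cannot show how often camera calls lists falsely in the real data. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. No library and no deposited column of counts was left out of the main comparisons.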

Results

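Gene expression was measured by sequencing total RNA from LAPC4 and LNCaP, human prostate cancer cell lines. Resistant lines had been selected in 0.5 uM palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6, and are called PDR1 (in both cell lines) and PDR2 (LNCaP). Cells of the 5 lines were seeded without drug and then kept for 24 h with vehicle or 0.5 uM palbociclib, with 3 libraries per group. Mean library totals (± SD, n = 3) for vehicle and palbociclib were 52.3 ± 1.55 and 49.0 ± 4.40 M (mega) counts in LAPC4 parental cells, and 45.8 ± 6.30 and 45.2 ± 2.41 M in LAPC4 PDR1. LNCaP parental libraries held 52.1 ± 2.21 and 48.5 ± 1.31 M, LNCaP PDR1 52.6 ± 0.404 and 50.5 ± 3.60 M, and LNCaP PDR2 47.2 ± 2.57 and 43.6 ± 3.23 M. In the comparisons of a pair of groups, values after gene names are log2 fold changes ± SE from 3 libraries against 3. Interaction values are differences of such changes. In the fit without the 2 LNCaP libraries, the palbociclib group of each LNCaP resistant line lacks a library. "Rose" and "fell" are used where edgeR's adjusted p was under 0.05. Shares of genes without overlap are of all genes tested, called or not. In them the normalized counts of the 3 libraries of one group all lie above or below those of the other, which chance gives for 10% of genes.

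A pair of LNCaP libraries stood apart from their groups. Over the 550 genes at least 2-fold apart between LNCaP PDR1 and PDR2 under vehicle, each resistant library was placed between PDR2 (0) and PDR1 (1). The library labelled PDR1 palbociclib replicate 3 lay at a median position of 0.0913, and the library labelled PDR2 palbociclib replicate 1 at 0.825. The other 4 palbociclib and 6 vehicle libraries lay within 0.113 of the mean of their own line. CDH3, which encodes P-cadherin, had 1727 to 1849 normalized counts in PDR1 vehicle libraries and 15.9 in the library labelled PDR1 palbociclib replicate 3. It had 1921 in the library labelled PDR2 palbociclib replicate 1, against 34.6 and 24.8 in the other PDR2 palbociclib libraries. Results of the comparisons that hold them were therefore also computed without these 2 libraries, an alternative chosen after seeing the data. Of 29 list calls with all libraries 27 stayed called in the same direction, and 13 were called without both but not with all libraries. Of 244 calls of genes that the naming rule picked 239 stayed. The 2 libraries enter vehicle comparisons and the parental response only through the filter, the scaling and the shared estimate of spread. Counts of genes still moved there. Under vehicle 7008 (LNCaP PDR1) and 9171 (LNCaP PDR2) genes passed without them, against 5671 and 8005 with all libraries.

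**Figure D1:**
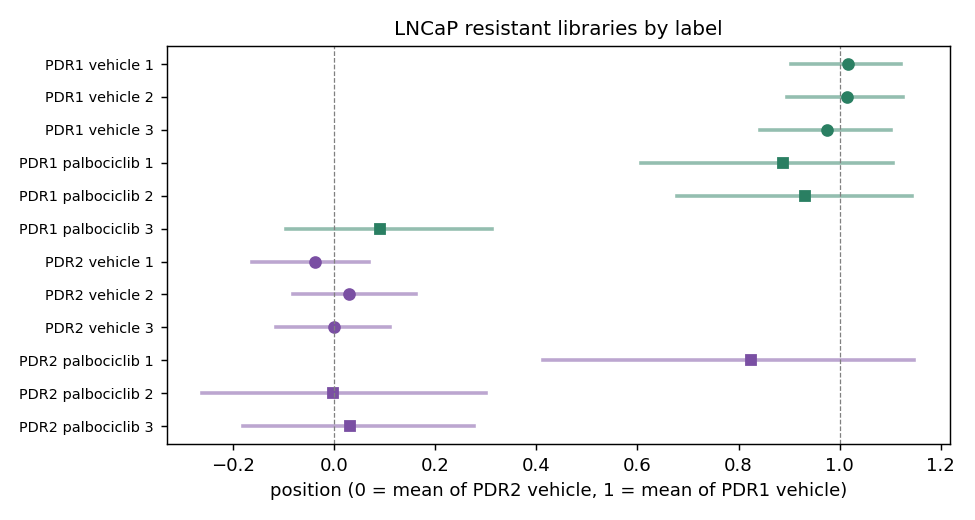
Median position of each LNCaP resistant library (horizontal axis, no unit) between the PDR2 vehicle mean (0) and the PDR1 vehicle mean (1) over 550 genes. Libraries are listed on the vertical axis, with bars for the quartiles, circles for vehicle, squares for palbociclib, green for libraries labelled PDR1 and purple for PDR2. Of the 12 libraries, 1 labelled PDR1 lies at 0.0913 and 1 labelled PDR2 at 0.825.

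The first question was how each line responded to 24 h of palbociclib. In LAPC4 parental cells, genes of DNA replication and of mitosis fell together. RRM2 (GeneID 6241), a subunit of ribonucleotide reductase, went from 8763 ± 181 to 631 ± 49.4 normalized counts (mean ± SD, n = 3), a change of -3.79 ± 0.08 (adjusted p = 1.19e-14). The proliferation marker MKI67 (GeneID 4288) fell from 10439 ± 655 to 1477 ± 225 (-2.82 ± 0.16, adjusted p = 5.86e-10). DDIT4 (GeneID 54541), an inhibitor of mTORC1 signalling, rose from 3093 ± 236 to 8629 ± 267 (1.48 ± 0.08, adjusted p = 3.69e-10). In all, 2992 of 15515 genes passed (1161 higher, 1831 lower), of which 462 changed at least 2-fold. With offsets for GC content and gene length 2129 were higher and 2100 lower. Of all genes tested 36.4% showed no overlap between libraries (10% by chance).

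All 56 measured E2F and S-phase genes fell, as did all 50 genes of G2 and mitosis, over all genes and adjusted over the list alone. Both lists had a median of -1.82 (E2F camera adjusted p = 1.07e-88, adjusted p = 3.25e-06 with an estimated correlation, and mitosis camera adjusted p = 2.98e-78, adjusted p = 0.000569 with an estimated correlation). Among them were the checkpoint adaptor CLSPN (-3.80), the exonuclease EXO1 (-3.35), the thymidylate synthase TYMS (-3.04), cyclin A2 (CCNA2, -2.53) and the kinesin KIF2C (-2.28). Of 24 RB and CDK core genes 1 rose, 9 fell and 14 did not pass (3 and 11 adjusted over the list alone, camera adjusted p = 0.000245, adjusted p = 0.0127 with an estimated correlation). Those that fell included E2F1 (-2.02 ± 0.07), the cyclins CCNE1 (-2.02) and CCNE2 (-2.44), CDK2 (-1.62), the pocket protein RBL1 (-2.04) and CDK4 (-0.42). The cyclin D1 gene CCND1 (0.37) and DUSP6, a phosphatase of ERK (0.29), rose. Panel genes that did not pass were RB1 (-0.19), CDKN1A (-0.08), CDKN2A (0.24) and KLK3 (0.43), which encodes prostate-specific antigen.

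Of 29 hypoxia and glycolysis genes 9 rose and none fell (11 rose and 1 fell adjusted over the list alone), among them ALDOC (0.73) and NDRG1 (0.88). The call was not kept with an estimated correlation (camera adjusted p = 0.0192, adjusted p = 0.541 with an estimated correlation). Amino acid and stress genes of the ATF4 list were lower, with 15 of 30 falling and 1 rising (17 and 2 adjusted over the list alone). They included asparagine synthetase ASNS (-0.54) and the amino acid transporter SLC7A5 (-0.65) (camera adjusted p = 0.00231, adjusted p = 0.541 with an estimated correlation). In the ribosome biogenesis list 8 of 32 fell (10 adjusted over the list alone), such as the nucleolar proteins NOP56 (-0.38) and FBL (-0.48) (camera adjusted p = 0.0074, adjusted p = 0.11 with an estimated correlation). Of 29 cholesterol and fatty acid synthesis genes 8 fell (9 adjusted over the list alone), including the desaturase FADS1 (-0.39) (camera adjusted p = 0.015, adjusted p = 0.541 with an estimated correlation). The hypoxia call was lost without parental palbociclib replicate 2 (adjusted p = 0.0603).

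LAPC4 PDR1 cells also lowered replication and mitosis genes under palbociclib. MKI67 went from 8813 ± 1551 to 4309 ± 915 normalized counts (-1.03 ± 0.15, adjusted p = 0.000511) and RRM2 from 11128 ± 519 to 6778 ± 160.4 (-0.72 ± 0.07, adjusted p = 5.38e-05). Of the mitosis list 46 of 50 fell (48 adjusted over the list alone, median -0.65, camera adjusted p = 2.45e-65, adjusted p = 0.00124 with an estimated correlation), among them the kinesin KIF20A (-0.96) and GTSE1 (-0.81). The E2F list had 42 of 56 lower (52 adjusted over the list alone, median -0.42, camera adjusted p = 9.37e-51, adjusted p = 4.2e-05 with an estimated correlation), among them TYMS (-0.71) and the primase subunit PRIM1 (-0.81). CDK2 (-0.52), CCNE1 (-0.36), CCNE2 (-0.68) and RBL1 (-0.66) fell, while E2F1 was at -0.23 and did not pass. The RB and CDK core had 5 of 24 lower (2 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.0943 with an estimated correlation), a call lost without palbociclib replicate 1 or 2 (adjusted p = 0.0677 and 0.0662). The lactate transporter SLC16A3 (1.31) and thymidine phosphorylase TYMP (0.99) were among the genes that rose most. Of 29 hypoxia genes 4 rose (8 adjusted over the list alone), such as NDRG1 (0.70) and ALDOC (0.56) (camera adjusted p = 1.3e-08, adjusted p = 0.122 with an estimated correlation). None of 23 luminal epithelial genes passed over all genes, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000568, adjusted p = 0.397 with an estimated correlation).

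In LAPC4 PDR1, 548 genes passed (128 higher, 420 lower), 15 of them at least 2-fold, and 23.2% of genes tested were without overlap (10% by chance). The count was 267 without vehicle replicate 1, 280 without vehicle replicate 3 and 356 without palbociclib replicate 3. A fit of only the 6 compared libraries gave 252, edgeR with no filter 913 and DESeq2 1054. The share higher, 23.4% in the main fit, depended on the processing. It was 44.2% with no filter, 38.7% by DESeq2 and 39.3% by the authors' deposited adjusted p. At a threshold of 0.01 it was 5.88%, and without vehicle replicate 1 7.49%.

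LNCaP parental cells lowered mitosis genes and part of the E2F list. GTSE1 (GeneID 51512), a microtubule-associated protein of the G2 and S phases, fell (-1.96 ± 0.11, adjusted p = 9.96e-10), and MKI67 from 5116 ± 485 to 1658 ± 274 normalized counts (-1.63 ± 0.13, adjusted p = 7.58e-08). Of 50 mitosis genes 48 fell (49 adjusted over the list alone, median -1.24, camera adjusted p = 4.62e-106, adjusted p = 0.00566 with an estimated correlation), including Aurora kinase B (AURKB, -1.85) and the securin PTTG1 (-1.92). Of 56 E2F genes 28 fell (43 adjusted over the list alone, median -0.56), such as TYMS (-1.50), thymidine kinase TK1 (-0.83) and the ligase LIG1 (-0.63) (camera adjusted p = 6.09e-37, adjusted p = 0.119 with an estimated correlation). Without the 2 libraries 43 fell and the call held with an estimated correlation (adjusted p = 0.00983). The CDK inhibitors CDKN2C (-1.77), CDKN1A (-0.72 ± 0.09) and CDKN2A (-0.70), CDK2 (-0.53) and E2F1 (-0.45) fell. CCNE1 (0.00) and KLK3 (0.24) did not pass. Of 24 RB and CDK core genes 5 fell and none rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.000172, adjusted p = 0.168 with an estimated correlation).

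In LNCaP parental cells, of 27 p53 targets 7 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 9.94e-07, adjusted p = 0.0469 with an estimated correlation), with the DNA repair factor DDB2 at -0.67 and TP53INP1 at 0.42. Of 30 ATF4 genes 2 fell (4 adjusted over the list alone), SLC7A5 (-0.76) and the serine synthesis enzyme PHGDH (-0.41) (camera adjusted p = 0.000557, adjusted p = 0.38 with an estimated correlation). Of 29 hypoxia genes 3 fell, among them EGLN3 (-0.50) and PFKP (-0.35) (camera adjusted p = 0.0194, adjusted p = 0.484 with an estimated correlation). The lysosome list was called higher (camera adjusted p = 0.0194, adjusted p = 0.38 with an estimated correlation), although the 1 member of 32 that passed, the glucuronidase GUSB, fell (-0.40), and 2 rose and 1 fell adjusted over the list alone. It was lost without palbociclib replicate 2 (adjusted p = 0.0502) or vehicle replicate 3 (0.159), and the hypoxia call without vehicle replicate 2 (0.154).

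In LNCaP parental cells 502 genes passed (87 higher, 415 lower), 135 of them at least 2-fold, and with offsets for GC content and length 224 were higher and 438 lower. Of genes tested 25.8% were free of overlap (10% by chance). The count was 334 without palbociclib replicate 1, 294 without palbociclib replicate 2 and 310 without vehicle replicate 2. It was 1085 (317 higher, 768 lower) with the 2 LNCaP resistant libraries left out of the fit, 762 by DESeq2, 1378 in a fit of only the compared libraries and 1619 in the authors' deposited table.

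In LNCaP PDR1, with the library labelled palbociclib replicate 3 included, few genes passed. SLC7A5 (-0.74 ± 0.09, adjusted p = 0.000651), the linker histone H1F0 (-0.81 ± 0.09, adjusted p = 0.000163), the transcription factor KLF4 (-1.08), CDKN1A (-0.50) and DHRS3, a retinal reductase (-1.17), fell. The 5 genes that rose were the telomerase subunit TERT (0.94 ± 0.16, adjusted p = 0.0122), TUBB4A (0.70), ZDHHC11 (0.59), LOC100506123 (1.32) and EMC3-AS1 (0.56). Of 50 mitosis genes 2 fell (29 adjusted over the list alone, median -0.39), KIF4A (-0.63) and GTSE1 (-0.57) (camera adjusted p = 2.33e-26, adjusted p = 0.281 with an estimated correlation), and MKI67 was at -0.60 and did not pass. No E2F gene passed, and the list was not called (median 0.01, although the test pointed lower, camera adjusted p = 0.386). Left out alone, palbociclib replicate 2 made it called lower (adjusted p = 0.000566) and palbociclib replicate 3 higher (0.00767). Of 27 p53 targets 1 fell (6 adjusted over the list alone, camera adjusted p = 2.85e-09, adjusted p = 0.0282 with an estimated correlation), as did 1 of 30 ATF4 genes (3 adjusted over the list alone, camera adjusted p = 0.00506, adjusted p = 0.63 with an estimated correlation) and 1 of 19 MAPK output genes (2 adjusted over the list alone, camera adjusted p = 0.00542, adjusted p = 0.0959 with an estimated correlation). The cholesterol list was called higher with none of 28 genes passing (camera adjusted p = 0.00514, adjusted p = 0.63 with an estimated correlation). These list calls held without the 2 libraries, for p53 (adjusted p = 1.4e-08), ATF4 (1.82e-15), MAPK (0.000306) and cholesterol (0.000306). In that fit hypoxia genes (lower, 0.000141), receptor tyrosine kinases and ligands (lower, 0.00767) and ribosome biogenesis genes (higher, 0.012) were called as well, none with an estimated correlation (0.397, 0.259 and 0.494). Without palbociclib replicate 2 the ATF4 (adjusted p = 0.182), MAPK (0.112) and cholesterol (0.459) calls were lost, and without palbociclib replicate 1 the ATF4 call (0.172).

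Without the 2 libraries, LNCaP PDR1 had 169 genes past the threshold (56 higher, 113 lower), of which 28 were shared with the fit of all libraries. There MKI67 (-0.49) and KIF20A (-0.52) fell, 11 mitosis genes fell (median -0.27), and so did 14 ATF4 genes, among them the pseudokinase TRIB3 (-0.95) and ATF3 (-0.78). The E2F list was then called higher (median 0.09, camera adjusted p = 0.000527), but not with an estimated correlation (adjusted p = 0.597), with 2 members rising, MCM3 (0.32) and ORC6 (0.46), and 1 falling, PRIM1 (-0.47).

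With all libraries 28 genes passed in LNCaP PDR1 (5 higher, 23 lower), 6 at least 2-fold, and 21 were higher and 37 lower with offsets for GC content and length. Of genes tested 17.4% were free of overlap (10% by chance). The count was 16 without palbociclib replicate 1, 12 without palbociclib replicate 3, 4 without vehicle replicate 1, 3 without vehicle replicate 2 and 92 without vehicle replicate 3. A fit of only the 6 compared libraries in edgeR gave 0, with 1842 genes at an unadjusted p under 0.05, while DESeq2 on all LNCaP libraries gave 246, edgeR with no filter 141 and the authors' deposited adjusted p 216.

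LNCaP PDR2, with the library labelled palbociclib replicate 1 included, lowered mitosis genes and changed others in both directions. KIF4A (-0.89 ± 0.11, adjusted p = 0.000304), the kinetochore protein CENPF (-0.81), the kinase NEK2 (-0.70) and MKI67 (-0.79 ± 0.13, adjusted p = 0.00244) fell. In the mitosis list 27 of 50 genes fell (38 adjusted over the list alone, median -0.49, camera adjusted p = 1.21e-26, adjusted p = 0.54 with an estimated correlation). With the 2 libraries left out 48 fell (median -0.75) and the call held with an estimated correlation (adjusted p = 0.0175). Of 56 E2F genes 1 rose and 3 fell, and the list was not called (median 0.02, although the test pointed lower, camera adjusted p = 0.562). In the fit that left both out 1 rose and 22 fell, and the list was called lower (camera adjusted p = 1.2e-09, adjusted p = 0.384 with an estimated correlation). CDKN1A (-0.55), CDKN2C (-0.63), thrombospondin THBS1 (-1.40) and KLF4 (-1.26) fell, and the disulfide isomerase PDIA2 (1.39) and relaxin RLN1 (1.33) rose. These calls held without the 2 libraries (THBS1 at an adjusted p of 3.4e-05), with KLF4 at -1.19, PDIA2 at 1.03 and RLN1 at 0.54. Of 30 ATF4 genes 6 fell (3 rose and 17 fell adjusted over the list alone), such as TRIB3 (-0.96) and SLC7A5 (-0.45) (camera adjusted p = 1.5e-05, adjusted p = 0.54 with an estimated correlation). Of 29 hypoxia genes 5 fell (6 adjusted over the list alone), such as EGLN3 (-0.44) and PGK1 (-0.36) (camera adjusted p = 0.0026, adjusted p = 0.553 with an estimated correlation), a call lost without vehicle replicate 2 (adjusted p = 0.0645). In the fit without both libraries 11 ATF4 and 5 hypoxia genes fell (camera adjusted p = 3.03e-06 and 0.00129). The p53 (0.00176) and RB and CDK core (0.0142) lists were called lower there but not with all libraries, and not with an estimated correlation (0.0802 and 0.244). Both were also called lower without palbociclib replicate 1 alone (camera adjusted p = 0.00281 and 0.0228), and the p53 list without vehicle replicate 1 alone (0.0472). The largest rise in the fit, CDH3 at 5.12, rested on the library labelled palbociclib replicate 1, and without the 2 libraries CDH3 was at 0.62 and did not pass.

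In LNCaP PDR2 1107 genes passed (563 higher, 544 lower), 55 at least 2-fold, and 24.0% of genes tested were free of overlap (10% by chance). A total of 1970 passed when both doubted libraries were left out (959 higher, 1011 lower), 935 of them shared. The count was 473 without palbociclib replicate 2, 2117 without palbociclib replicate 3, 510 without vehicle replicate 2 and 110 without vehicle replicate 3, and a fit of only the 6 compared libraries gave 51. GC and length offsets gave 627, the authors' deposited adjusted p 716 and DESeq2 1940.

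**Figure D2:**
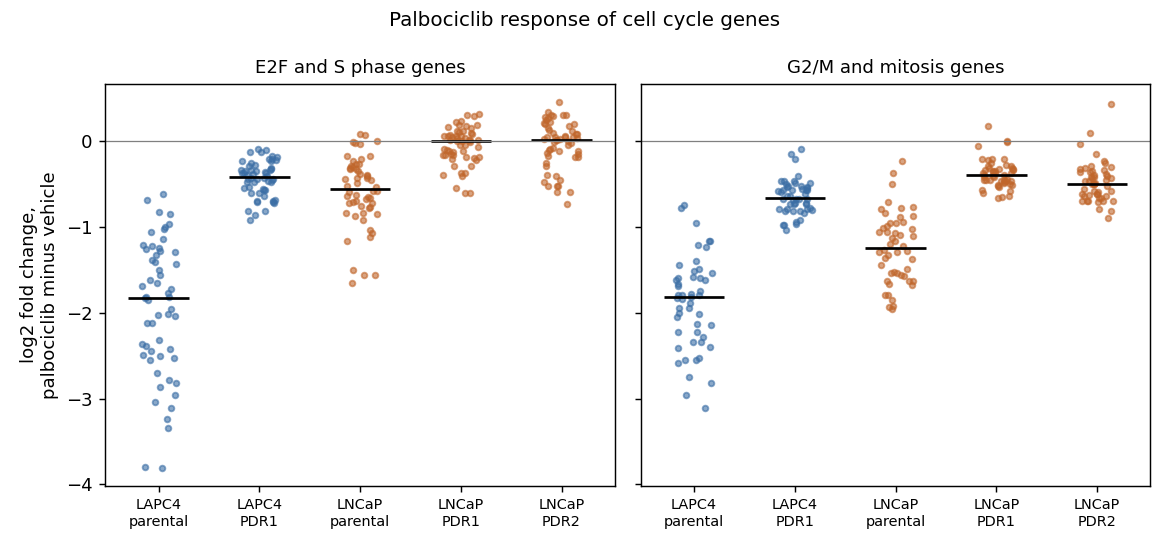
Log2 fold change (palbociclib against vehicle, vertical axis) of each measured gene of the E2F and S-phase list and of the G2 and mitosis list in the 5 lines, LAPC4 in blue and LNCaP in orange. Each point is a gene and the black line the median, which for mitosis genes runs from -1.82 in LAPC4 parental cells to -0.39 in LNCaP PDR1.

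Whether resistant lines responded differently from their parental line was tested directly as an interaction. In LAPC4 PDR1 the falls of replication and mitosis genes were smaller than in parental cells. The difference of log2 fold changes was 3.08 ± 0.10 for RRM2 (adjusted p = 1.72e-11), 2.71 for EXO1, 1.79 ± 0.10 for E2F1 (adjusted p = 6.95e-09), 1.65 for CCNE1, 1.10 for CDK2 and 1.79 ± 0.21 for MKI67 (adjusted p = 2.24e-05). Of 56 E2F genes 54 passed (56 adjusted over the list alone, median 1.37, camera adjusted p = 7.72e-124, adjusted p = 9.67e-07 with an estimated correlation), and of 50 mitosis genes 48 (50 adjusted over the list alone, median 1.22, camera adjusted p = 3.84e-91, adjusted p = 0.000352 with an estimated correlation), all with positive differences. The RB and CDK core had 6 of 24 positive (camera adjusted p = 0.000225, adjusted p = 0.0107 with an estimated correlation). Negative differences included DDIT4 (-0.80 ± 0.11, adjusted p = 0.000143) and COLCA2 (-1.38). In the ATF4 list 1 gene passed with a positive and 1 with a negative difference (5 and 1 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.633 with an estimated correlation), a call lost without PDR1 palbociclib replicate 3 (adjusted p = 0.069). In all 562 of 15515 genes differed (503 positive, 59 negative).

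LNCaP PDR1, with the library labelled palbociclib replicate 3, differed from its parental line in 53 genes (51 positive, 2 negative), and in 260 (243 positive, 17 negative) without the 2 libraries. DESeq2 gave 130, a fit of only the compared libraries 105 and edgeR with no filter 85. GTSE1 (1.39 ± 0.15, adjusted p = 0.00011), MKI67 (1.02 ± 0.18, adjusted p = 0.0102) and TK1 (0.88) had positive differences (1.46, 1.13 and 0.90 without the 2 libraries). The semaphorin SEMA3C had a negative one (-1.12, or -0.92 without them). The largest positive difference that the rule named was that of NMU (1.61 ± 0.19, adjusted p = 0.000473). All 17 genes that the rule named and that passed stayed called without the 2 libraries. The mitosis list had 18 of 50 genes passing (46 adjusted over the list alone, median 0.87, camera adjusted p = 2.65e-65, adjusted p = 0.0417 with an estimated correlation), and of 56 E2F genes 4 (31 adjusted over the list alone, median 0.50, camera adjusted p = 2.35e-31, adjusted p = 0.24 with an estimated correlation), against 44 and 37 without the 2 libraries. The RB and CDK core was called higher with 1 passing (camera adjusted p = 0.0192, adjusted p = 0.622 with an estimated correlation), and the ribosome (camera adjusted p = 0.0266, adjusted p = 0.885 with an estimated correlation) and cholesterol (camera adjusted p = 0.038, adjusted p = 0.934 with an estimated correlation) lists with none. All 3 were called without the 2 libraries too (camera adjusted p = 0.000145, 0.00887 and 0.00887). The ATF4 and lysosome lists were called lower in that fit (0.00887 and 0.00887) but not with all libraries, and not with an estimated correlation (0.328 and 0.401). The lysosome list was also called lower without PDR1 palbociclib replicate 3 alone (camera adjusted p = 0.0164). The RB and CDK call was lost without PDR1 palbociclib replicate 2 (adjusted p = 0.354), PDR1 vehicle replicate 3 (0.105) or parental vehicle replicate 3 (0.0575). The ribosome call was lost without PDR1 palbociclib replicate 2 (0.559), PDR1 vehicle replicate 3 (0.0927), parental palbociclib replicate 1 (0.0617) or parental vehicle replicate 3 (0.0575). The cholesterol call was lost without PDR1 palbociclib replicate 2 (0.696), PDR1 vehicle replicates 2 and 3 (0.164 and 0.109), parental palbociclib replicates 1 and 2 (0.0617 and 0.0632), or parental vehicle replicates 2 and 3 (0.0549 and 0.218). The count was 35, 33 and 101 without PDR1 palbociclib replicates 1, 2 and 3, and 30 without PDR1 vehicle replicate 1 or 2. It was 28 and 23 without parental palbociclib replicates 1 and 2, and 31 and 34 without parental vehicle replicates 2 and 3.

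In LNCaP PDR2, with the library labelled palbociclib replicate 1, 103 genes differed from the parental response (90 positive, 13 negative), and 247 (194 positive, 53 negative) without the 2 libraries. DESeq2 gave 418, edgeR with no filter 213, a fit of only the compared libraries 53, GC and length offsets 42 and a replicate block 38. GTSE1 (1.35 ± 0.15, adjusted p = 0.000189), TK1 (0.89), MKI67 (0.84) and CDKN2A (1.19) had positive differences (1.18, 0.70, 0.69 and 1.01 without the 2 libraries). The largest positive difference that the rule named was that of LRRC26 (1.83 ± 0.42, adjusted p = 0.0497). Negative ones included CCDC82 (-0.99 ± 0.22, adjusted p = 0.0409) and TRIM59 (-0.75 ± 0.11, adjusted p = 0.00445). All 24 genes that the rule named and that passed stayed called without the 2 libraries. Of 50 mitosis genes 15 passed (42 adjusted over the list alone, median 0.74, camera adjusted p = 1.8e-33, adjusted p = 0.244 with an estimated correlation) and of 56 E2F genes 4 (28 adjusted over the list alone, median 0.51, camera adjusted p = 1.92e-20, adjusted p = 0.527 with an estimated correlation), against 24 and 9 without the 2 libraries (camera adjusted p = 1.7e-34 and 1.15e-14). The count was 55 and 353 without PDR2 palbociclib replicates 1 and 3, and 36, 15 and 7 without PDR2 vehicle replicates 1, 2 and 3. It was 9 without parental palbociclib replicate 1 or 2, 10 without parental vehicle replicate 1 or 2, and 291 without parental vehicle replicate 3.

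The next question was how resistant lines differed from parental lines in the absence of drug. LAPC4 PDR1 had less RB1 RNA, and CDK inhibitors differed in both directions. RB1 (GeneID 5925), which encodes the retinoblastoma protein that CDK4 and CDK6 phosphorylate, was lower (-0.92 ± 0.09, adjusted p = 4.37e-07). CDKN2A (GeneID 1029), the source of the CDK4 inhibitor p16, was at 865 ± 156 against 114 ± 11.1 normalized counts (2.92 ± 0.19, adjusted p = 4.47e-09), and CDKN1A, which encodes p21, was also higher (1.59 ± 0.13, adjusted p = 5.32e-08). CDKN2B was higher (1.99) and CDKN2C lower (-0.87 ± 0.07, adjusted p = 9.39e-08). CCNE1 (0.88), CDK6 (0.83), CCND1 (0.62) and CCNE2 (0.28) were higher, while MKI67 (-0.24), E2F1 (-0.03) and CDK2 (0.06) did not pass. KLK3 (-3.92, 4.21 ± 2.45 against 63.0 ± 10.5 counts) and KLK4 (-5.45) were lower.

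Cholesterol and fatty acid synthesis genes were lower in LAPC4 PDR1 under vehicle, 25 of 29 with none higher (25 adjusted over the list alone, median -0.59, camera adjusted p = 2.44e-11, adjusted p = 0.184 with an estimated correlation). They included the desaturases FADS1 (-1.41) and FADS2 (-1.31). Mitosis genes were lower for 25 of 50 members and higher for 4 (28 and 4 adjusted over the list alone, camera adjusted p = 0.000258, adjusted p = 0.558 with an estimated correlation), such as CDC20 (-0.81) and PLK1 (-0.67), and the E2F list, with 20 higher and 10 lower, was not called (camera adjusted p = 0.0922). A large single difference was a rise of the neuronal adaptor APBA2 (9.60). CBLN4, at 0 in PDR1 vehicle libraries, was at least 696-fold lower, and LONRF2, with 1 parental count, was higher by a ratio of 1108 (counting interval 199 to 43778). In all 7089 of 15515 genes differed (3234 higher, 3855 lower), 1802 at least 2-fold, and 59.4% of genes tested were free of overlap (10% by chance).

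LNCaP PDR1 also had less RB1 under vehicle, at 1099 ± 79.6 against 3519 ± 293 normalized counts (-1.68 ± 0.11, adjusted p = 4.38e-10). KLK3 (GeneID 354) was at 979 ± 41.5 against 79438 ± 5207 (-6.34 ± 0.40, adjusted p = 1.76e-10). CDK6 (-2.08) and CDKN1A (-0.69) were lower, and CDKN2A (0.59), E2F1 (0.38) and MKI67 (0.34) higher. Of 50 mitosis genes 17 were higher and 1 lower (20 and 1 adjusted over the list alone, camera adjusted p = 0.000681, adjusted p = 0.703 with an estimated correlation), and of 56 E2F genes 14 were higher and 2 lower (camera adjusted p = 0.0404, adjusted p = 0.732 with an estimated correlation), such as BRCA2 (1.18) and TK1 (0.69). The E2F call was lost without PDR1 vehicle replicate 1 (adjusted p = 0.0817) or parental vehicle replicate 1 (0.0757). Cholesterol genes were lower (15 of 28 lower, 2 higher, 16 and 3 adjusted over the list alone, camera adjusted p = 0.000681, adjusted p = 0.586 with an estimated correlation), with fatty acid synthase FASN at -1.38. Ribosome biogenesis genes were also lower (11 of 32 lower, 1 higher, camera adjusted p = 0.00865, adjusted p = 0.586 with an estimated correlation). The ETS factor ETV1, which LNCaP cells express from a rearranged locus, was at 4.48 ± 4.62 against 11069 ± 822 counts (-11.22), and the protocadherin PCDH7 at 12559 ± 769 against 8.56 ± 3.02 (10.48). S100A7, at 0 in PDR1, was at least 287-fold lower, and RND3, with 2 parental counts, was higher by a ratio of 2333 (counting interval 646 to 19267). In all 5671 of 16070 genes differed (2789 higher, 2882 lower), 1567 at least 2-fold, and 51.4% of genes tested were free of overlap (10% by chance). With the 2 doubted libraries left out of the fit 7008 differed (3520 higher, 3488 lower).

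LNCaP PDR2 differed from parental cells in many of these genes under vehicle, with RB1 at 1497 ± 112 normalized counts (-1.23 ± 0.11, adjusted p = 2.72e-08) and KLK3 at 2849 ± 278 (-4.80 ± 0.37, adjusted p = 3.18e-09). CDK6 (-2.58), CDKN1A (-1.07) and CCND1 (-0.29) were lower and MKI67 (0.36) higher, while CDKN2A (0.06) did not pass. Of 27 p53 targets 15 were lower and 2 higher (16 and 2 adjusted over the list alone, camera adjusted p = 0.000923, adjusted p = 0.309 with an estimated correlation), such as SESN1 (-1.46), PLK2 (-2.19) and FAS (-1.91). The ATF4 list had 18 of 30 higher and 3 lower (median 0.40, camera adjusted p = 0.000929, adjusted p = 0.461 with an estimated correlation), with ATF4 itself at 1.08 and ASNS at 0.85. Cholesterol genes (17 of 28 lower, 18 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.99e-05, adjusted p = 0.461 with an estimated correlation) and ribosome biogenesis genes (18 of 32 lower, 1 higher, camera adjusted p = 0.000929, adjusted p = 0.461 with an estimated correlation) were lower. FCAMR and SPAG16, at 0 in PDR2, were at least 652-fold and 439-fold lower. In all 8005 genes differed (4007 higher, 3998 lower), 2128 at least 2-fold, and 61.4% of genes tested were free of overlap (10% by chance). With the 2 doubted libraries left out of the fit 9171 differed (4568 higher, 4603 lower).

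**Figure D3:**
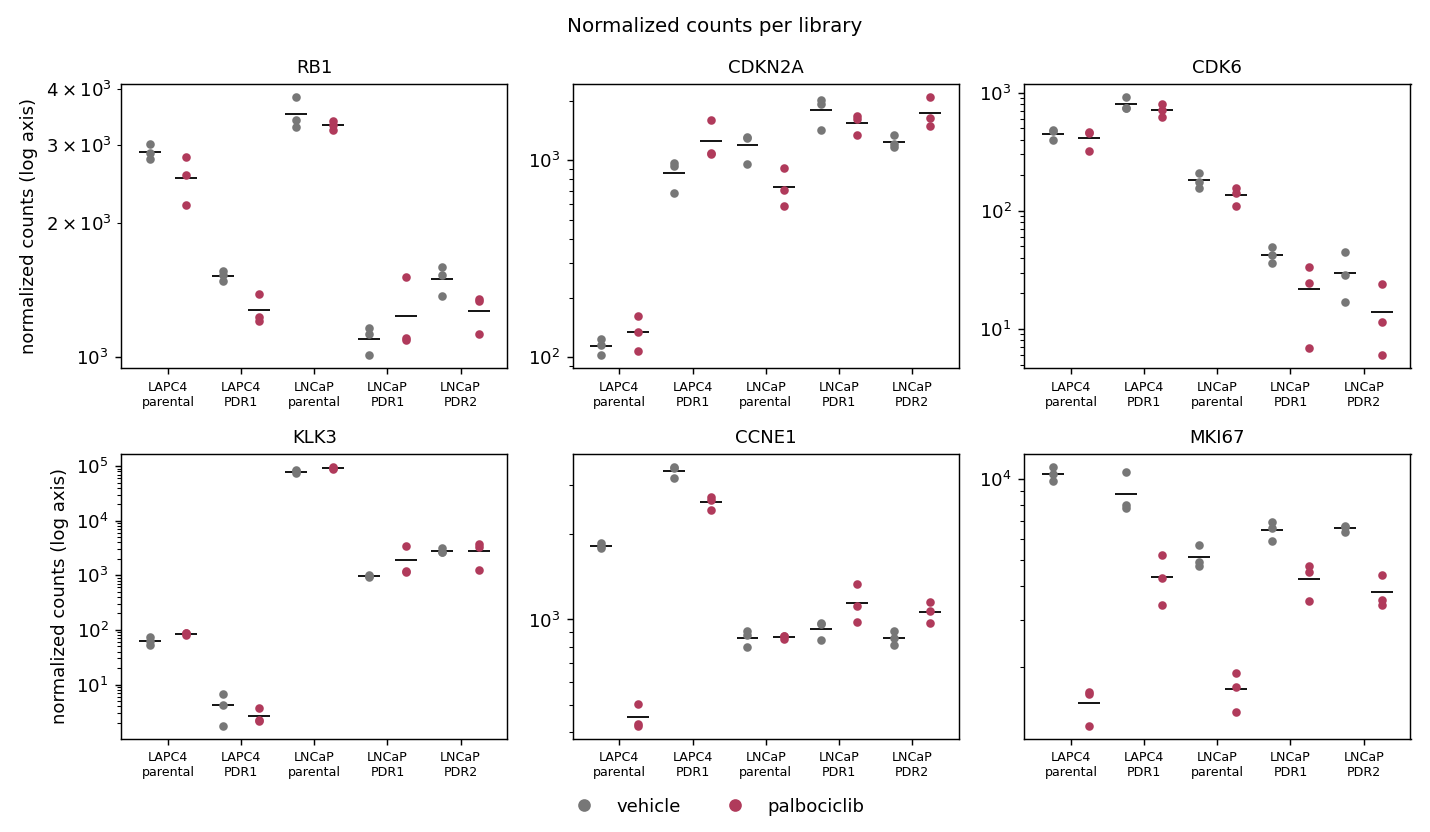
Normalized counts per library (vertical axis, log scale, values under 0.5 drawn at 0.5) of RB1, CDKN2A, CDK6, KLK3, CCNE1 and MKI67 in the 10 groups, grey for vehicle and red for palbociclib, with the mean of 3 libraries as a black line. RB1 is lower in each resistant line than in its parental line under vehicle.

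Whether resistant lines moved the same genes was tested as the overlap of these vehicle comparisons. LAPC4 PDR1 and LNCaP PDR1 shared 626 higher and 819 lower genes, where independent lists would share 516 and 671 (Fisher's exact test across genes, which are not independent replicates, two-sided p = 4.46e-09 and 7.99e-13). Another 1278 genes passed in opposite directions, where independent lists would give 1180.5, so part of the excess is not agreement in direction. For LAPC4 PDR1 and LNCaP PDR2 the shared counts were 936 and 1200, against 744 and 945 (p = 4.19e-19 and 8.41e-28, Fisher's exact test), with 1459 opposite (1683.8 for independent lists), among 14658 genes tested in both cell lines. That deficit of opposite genes did not hold for genes changed at least 2-fold in both lines. There 180 were opposite (76.3 for independent lists), beside 227 shared higher and 67 shared lower (65.2 and 21.5). For LAPC4 PDR1 and LNCaP PDR1, 159 such genes were opposite (55), beside 153 and 61 shared (47.2 and 15.5). LNCaP PDR1 and PDR2, which share their parental libraries, had 2191 higher and 2296 lower genes in common, against 695 and 717 for independent lists, and 9 in opposite directions. Compared directly under vehicle, these resistant lines differed in 4643 of 15721 genes (2375 higher in PDR1, 2268 higher in PDR2), 550 of them at least 2-fold.

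Resistant and parental cells were then compared with both under palbociclib. LAPC4 PDR1 had more RNA of replication genes than parental cells, with RRM2 at 6778 ± 160.4 against 631 ± 49.4 normalized counts (3.42 ± 0.08, adjusted p = 1.04e-14) and CCNE1 higher by 2.53 ± 0.08 (adjusted p = 1.01e-12). All 56 E2F genes were higher (median 1.45, camera adjusted p = 2.12e-38, adjusted p = 9.01e-05 with an estimated correlation), such as the methylation reader UHRF1 (2.55), and of 50 mitosis genes 46 were higher and 1 lower (median 1.01, camera adjusted p = 1.4e-21, adjusted p = 0.0398 with an estimated correlation). E2F1 (1.76), CDK2 (1.17), MKI67 (1.55), CDKN2A (3.21) and CDKN1A (1.82) were higher and RB1 (-0.99) and DUSP6 (-0.46) lower. Of 24 RB and CDK core genes 16 were higher and 6 lower (camera adjusted p = 0.00645, adjusted p = 0.0437 with an estimated correlation). Cholesterol genes were lower (23 of 29, camera adjusted p = 1.2e-09, adjusted p = 0.0787 with an estimated correlation). GALNT18, at 0 in parental palbociclib libraries, was at least 344-fold higher. In all 8045 genes differed (3995 higher, 4050 lower), 2080 at least 2-fold, and 54.4% of genes tested were free of overlap (10% by chance).

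LNCaP PDR1 under palbociclib, with the library labelled replicate 3, had more mitosis and replication RNA than treated parental cells. GTSE1 (1.70 ± 0.11, adjusted p = 1.29e-10), MKI67 (1.36), TK1 (1.58), E2F1 (0.92), CCNE1 (0.40), CCNE2 (0.84), CDK2 (0.71) and CDKN2A (1.07) were higher, and RB1 (-1.42), CDK6 (-2.64) and KLK3 (-5.59) lower. Without the 2 libraries MKI67 was at 1.48, E2F1 at 1.01, RB1 at -1.60 and KLK3 at -6.32. Mitosis genes were higher for 49 of 50 members (median 1.12, camera adjusted p = 7.93e-23, adjusted p = 0.538 with an estimated correlation), and of 56 E2F genes 48 (50 adjusted over the list alone, median 0.62, camera adjusted p = 3.57e-13, adjusted p = 0.538 with an estimated correlation), none lower in either list. In the fit without both libraries 48 and 53 were higher. Cholesterol genes were lower, 15 of 28 with 4 higher (camera adjusted p = 0.044, adjusted p = 0.623 with an estimated correlation). The cholesterol call was lost without PDR1 palbociclib replicate 1 (adjusted p = 0.116) or 3 (0.0529) or parental palbociclib replicate 3 (0.0768), and without the 2 doubted libraries (0.0701). RND3, at 0 in parental palbociclib libraries, was at least 1018-fold higher. In all 7026 genes differed (3647 higher, 3379 lower), 1954 at least 2-fold, and 7260 differed without the 2 libraries. Of genes tested 56.0% were free of overlap (10% by chance).

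LNCaP PDR2 under palbociclib, with the library labelled replicate 1, showed higher GTSE1 (1.62), MKI67 (1.19 ± 0.13, adjusted p = 2.16e-07), TK1 (1.56), E2F1 (0.66), CCNE1 (0.30) and CCNE2 (0.60). RB1 (-1.38), CDK6 (-3.29) and KLK3 (-5.08) were lower and DUSP6 (0.90) higher. Without the 2 libraries MKI67 was at 1.05, E2F1 at 0.48, RB1 at -1.32 and KLK3 at -4.76, while CCNE1 (0.22) and CCNE2 (0.11) no longer passed. Of 50 mitosis genes 43 were higher (44 adjusted over the list alone, median 0.88, camera adjusted p = 1.15e-11, adjusted p = 0.58 with an estimated correlation), and 41 without the 2 libraries. Of 56 E2F genes 30 were higher and 2 lower (camera adjusted p = 0.000833, adjusted p = 0.664 with an estimated correlation), and without the 2 libraries, or without the library labelled replicate 1 alone (adjusted p = 0.123), this list was not called. The p53 targets were lower, 16 of 27 with 5 higher (camera adjusted p = 0.0158, adjusted p = 0.58 with an estimated correlation). Cholesterol (17 of 28 lower, camera adjusted p = 0.000374, adjusted p = 0.58 with an estimated correlation) and ribosome biogenesis (17 of 32 lower, camera adjusted p = 0.0473, adjusted p = 0.591 with an estimated correlation) genes were lower, and ATF4 genes higher (17 of 30, camera adjusted p = 0.0363, adjusted p = 0.58 with an estimated correlation). All 4 held without the 2 libraries, for p53 (adjusted p = 0.00272), cholesterol (3.77e-05), ribosome (0.00548) and ATF4 (0.000984) genes. The ATF4 call was lost without PDR2 palbociclib replicate 2 (0.0517) or 3 (0.0959), and the ribosome call without either (0.139 and 0.0754) or parental palbociclib replicate 2 or 3 (0.0678 and 0.0718). RND3 was at least 921-fold higher and MYL9 at least 418-fold lower. In all 9143 genes differed (4822 higher, 4321 lower), 2495 at least 2-fold, and 9478 differed without the 2 libraries. Of genes tested 60.2% were free of overlap (10% by chance).

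A deposited table also set LNCaP PDR2 under palbociclib against parental cells under vehicle, so that line and treatment differ together. RB1 (-1.47), KLK3 (-4.84), CDKN1A (-1.62), CDK6 (-3.71) and MKI67 (-0.43 ± 0.13, adjusted p = 0.00649) were lower, and CCNE1 (0.30), CDKN2A (0.55), TK1 (0.73) and carbonic anhydrase CA9 (3.51) higher. Leaving out the 2 libraries, RB1 was at -1.41, KLK3 at -4.52 and MKI67 at -0.58, while CCNE1 (0.22) no longer passed. Of 27 p53 targets 18 were lower and 3 higher (camera adjusted p = 6.02e-05, adjusted p = 0.132 with an estimated correlation), and of 50 mitosis genes 22 were lower and 1 higher (camera adjusted p = 8.86e-05, adjusted p = 0.658 with an estimated correlation), such as PLK1 (-1.11). Cholesterol (18 of 28 lower, camera adjusted p = 8.86e-05, adjusted p = 0.624 with an estimated correlation), ribosome biogenesis (17 of 32 lower, 5 higher, camera adjusted p = 0.0393, adjusted p = 0.624 with an estimated correlation) and hypoxia genes (16 of 29 lower, 6 higher, camera adjusted p = 0.0439, adjusted p = 0.624 with an estimated correlation) were lower. Without PDR2 palbociclib replicate 2, or parental vehicle replicate 1 or 2, the ribosome (adjusted p = 0.0953, 0.0567 and 0.0511) and hypoxia (0.0627, 0.0567 and 0.104) calls were lost. In the fit without both doubted libraries the calls held for p53 (adjusted p = 6.21e-06), mitosis (1.87e-11), cholesterol (8.75e-06), ribosome (0.00319) and hypoxia (0.0362) genes. Called lower there, but not with all libraries, were the E2F (2.99e-05) and RB and CDK core (0.027) lists. In the same way the ATF4 (0.0333) and receptor tyrosine kinase (0.0485) lists were called higher. None of these held with an estimated correlation (0.459 for E2F and 0.369 for the others). Without PDR2 palbociclib replicate 1 alone, the E2F (camera adjusted p = 0.000414) and RB and CDK core (0.0329) lists were called lower as well. In all 8807 genes differed (4483 higher, 4324 lower), 2274 at least 2-fold, and 9335 differed without the 2 libraries. Of genes tested 56.0% were free of overlap (10% by chance).

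Some lists were called in none of the 15 comparisons with all libraries. Their lowest camera adjusted p was 0.179 for receptor tyrosine kinases and ligands, 0.0872 for the senescence-associated secretory phenotype, 0.179 for basal and stem genes and 0.111 for interferon and MHC genes. The receptor list was called lower in the response of LNCaP PDR1 without palbociclib replicate 3 alone (0.0219). The lowest value was 0.179 for mesenchymal, 0.179 for neuroendocrine, 0.209 for leukocyte and 0.363 for fibroblast or endothelial genes. Of 16 leukocyte markers 13 had a mean under 10 normalized counts in each cell line, and of 16 fibroblast or endothelial markers 12 in LAPC4 and 10 in LNCaP.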

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

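The tests of exchanged labels, of mixing and of a response of the whole group, the comparison with the removal of other LAPC4 PDR1 libraries, and the values of calls lost with offsets, were chosen only after the results were seen. So was the fit of all 30 libraries. The offsets for GC content and length were added after seeing the data, with what they should show written before their result was seen. The other tests were chosen before their results were seen.

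The library labelled LNCaP PDR1 palbociclib replicate 3 and the library labelled LNCaP PDR2 palbociclib replicate 1 were out of place among the resistant libraries. A response of the whole group is argued against, since the other 4 palbociclib libraries moved from their line by at most 0.113 on the scale between the lines. Mixing of the lines is argued against too, by genes at least 8-fold higher in the line of the label. Above the vehicle baseline of the other line, they kept 0.753% (27 genes) and 0.382% (17 genes) of that line's level. The positions of 0.0913 and 0.825 are what an exchange of these labels would give, so exchanged labels may explain the pattern, at a stage the tables do not show. No biological explanation was tested, and the groups were kept as labelled.

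LNCaP PDR1 and PDR2 shared their differences from parental cells under vehicle, with a covariance of log2 fold changes of 0.851 across genes. Spread between the shared parental libraries does not account for it, since the highest covariance in 20 simulations without any change was 0.0269. A difference carried by all parental libraries would enter both comparisons. The simulations did not hold one, so they cannot decide on it. LAPC4 cells in the resistant cultures are argued against, since genes abundant in LAPC4 and near absent in LNCaP parental cells reached a median of at most 0.158% of their LAPC4 level (58 genes). Also open, and possible explanations of the pattern, are selection by the same drug or a common origin of the resistant lines, neither of which was tested.

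Palbociclib raised 128 genes in LAPC4 PDR1, and these were richer in GC than other genes (median 62.3% against 50.2% of all tested). A trend with GC content and length is argued against as the whole cause, since 77 of the 128 stayed called with offsets for both. Over all 128 the median log2 fold change went from 0.44 (interquartile range 0.197) to 0.34 (0.237), with a median SE of 0.104 before the offsets. In the 77 that stayed called it went from 0.48 (0.209) to 0.41 (0.188). In the 51 that lost the call it went from 0.43 (0.198) to 0.20 (0.131) and was smaller in all 51, while their median SE went from 0.104 to 0.0835 and was larger in 5. Those calls ended with smaller effects, not with a larger spread. Without palbociclib replicate 3 of LAPC4 PDR1, 36 stayed called, but without the other libraries 19 (vehicle 1), 65 (vehicle 2), 27 (vehicle 3), 89 (palbociclib 1) and 77 (palbociclib 2) did, so whether 1 library makes the pattern cannot be told apart from the loss of a replicate. Of the 128, 62.5% also rose in LAPC4 parental cells, against at most 19.5% in 10000 random sets matched on expression, so a response shared with the parental line may explain part of it. The random sets were not matched on GC content, so they cannot tell such a response from a GC trend present in both lines.

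Differences of palbociclib response between resistant and parental lines, by the interaction test, were found for 562 genes in LAPC4 PDR1, 53 in LNCaP PDR1 and 103 in LNCaP PDR2. In LAPC4 PDR1 the median difference was 1.37 for E2F genes, 1.22 for mitosis genes and 0.217 for the RB and CDK core. The genes named there were RRM2 (3.08), EXO1 (2.71), E2F1 (1.79), CCNE1 (1.65), CDK2 (1.10), MKI67 (1.79), COLCA2 (-1.38) and DDIT4 (-0.80). In LNCaP PDR1 the median difference was 0.867 for mitosis genes, and the genes named included GTSE1 (1.39), MKI67 (1.02), TK1 (0.88) and SEMA3C (-1.12). In LNCaP PDR2 they included GTSE1 (1.35), MKI67 (0.835), TK1 (0.89) and CDKN2A (1.19). By their count, other splits of the samples do not exclude chance, since 2, 5 and 4 of 33 splits, the real ones included, gave as many genes as the real ones (562, 53 and 103), with 2038, 244 and 136 in the highest other split. This is a weak test. Of the 1, 4 and 3 other splits, 1, 3 and 3 exchange all parental palbociclib and vehicle labels and so carry the response itself, a structure of the samples. The other 31 splits gave 0 in LAPC4 PDR1, and the 29 others in LNCaP gave at most 105 (PDR1) and 99 (PDR2). Such splits mix treated and vehicle libraries, which puts the response into the spread.

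Between cell lines, in the fit of all 30 libraries, the palbociclib response of parental cells differed in 597 genes (LAPC4 minus LNCaP), and the vehicle difference of LAPC4 PDR1 from its parent differed from that of LNCaP PDR1 in 6415 and of LNCaP PDR2 in 7006. The test was of the difference itself.

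For the 12 comparisons of 3 libraries with 3, there are 10 splits, too few for a share under 0.05, and 1 of the 10 (the real one) gave as many genes in each. The highest other split gave 0 in edgeR except for palbociclib in LNCaP PDR2, where it gave 55 against the real 1107. The real counts were 2992, 548, 502 and 28 for palbociclib in LAPC4 parental, LAPC4 PDR1, LNCaP parental and LNCaP PDR1. They were 7089, 5671 and 8005 for LAPC4 PDR1, LNCaP PDR1 and LNCaP PDR2 against parental under vehicle, 8045, 7026 and 9143 under palbociclib, and 8807 for LNCaP PDR2 under palbociclib against parental vehicle.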

How the results depend on the processing

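Fits without the 2 doubted libraries, GC and length offsets, the authors' deposited adjusted p and the fit of all 30 libraries were chosen after seeing the data, while the other alternatives were planned. A pseudocount alternative was not run because the tables hold counts, another order of subtraction gives identical contrasts in 1 linear model, and adjustment over all genes tested is what edgeR already does, so it was applied to DESeq2 without independent filtering. Resistant against parental counts stayed within 1.5 times of the value reported except under a minimum log2 fold change. Simulated 1.5-fold changes were recovered for 68% of genes in LAPC4 and 74% in LNCaP. Of single-gene results, DESeq2 left 737 with the same call (3 lost it, 36 gained it), its size factors 781 (4 lost), GC and length offsets 732 (34 lost, 19 gained), no filter 763 (2 lost, 20 gained) and leaving out 1 library 5049 (484 lost, 29 gained). Of list results, called or not, an estimated correlation left 247 unchanged and ended 53 calls, and a correlation of 0.05 left 272 unchanged and ended 28 calls. Ranks left 290 unchanged (3 calls lost, 7 gained). The unchanged results include lists that were not called in either version. Leaving out 1 library ended 44 list calls in 19 lists and comparisons, each given with that comparison. It also gave list calls that the fit of all libraries did not, not all of which are given. In LAPC4 PDR1 under vehicle, the luminal epithelial and lysosome lists were each called without PDR1 vehicle replicate 1 (camera adjusted p = 0.0287) or 2 (0.0187). They were also called without parental vehicle replicate 1 (0.0424) or 3 (0.0314). The cause was not tested for any change below, except that fewer genes pass a stricter threshold by construction and fits with fewer libraries have fewer samples.

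Counts past a minimum absolute log2 fold change of 1 were 462 (LAPC4 parental), 15 (LAPC4 PDR1), 135 (LNCaP parental), 6 (LNCaP PDR1) and 55 (LNCaP PDR2) for palbociclib. For resistant against parental they were 1802, 1567 and 2128 under vehicle (LAPC4 PDR1, LNCaP PDR1, LNCaP PDR2) and 2080, 1954 and 2495 under palbociclib, 2274 for LNCaP PDR2 under palbociclib against parental vehicle, and 215, 26 and 29 for the interactions. The overlaps of resistant lines in the same direction under vehicle were 214 (LAPC4 PDR1 with LNCaP PDR1), 294 (with PDR2) and 1219 (LNCaP PDR1 with PDR2). In opposite directions there were 159, 180 and 3 genes, where independent lists would give 55, 76.3 and 100.6. At a threshold of 0.01 palbociclib changed 1777, 221, 291, 6 and 170 genes in the same order of lines, and the interactions held 359, 15 and 9.

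DESeq2 gave 1054 genes for palbociclib in LAPC4 PDR1, 762 in LNCaP parental, 246 in LNCaP PDR1 and 1940 in LNCaP PDR2, and 130 and 418 for the LNCaP interactions. Without its independent filtering it gave 848 (LAPC4 PDR1), 175 (LNCaP PDR1), 108 and 279, and edgeR with no filter 913, 141, 85 and 213. Fits of only the compared libraries gave 252 (LAPC4 PDR1), 1378 (LNCaP parental), 0 (LNCaP PDR1, edgeR, with 1842 at an unadjusted p under 0.05 and 246 by DESeq2 on all libraries) and 51 (LNCaP PDR2), and 105 and 53 for the interactions. GC and length offsets gave 58 in LNCaP PDR1, 627 in LNCaP PDR2 and 42 for the PDR2 interaction. In LAPC4 parental cells the share higher went from 38.8% to 50.3% (2129 higher, 2100 lower) and in LNCaP parental cells from 17.3% to 33.8% (224 higher, 438 lower) with these offsets. In LNCaP PDR1 it went from 17.9% to 36.2% (21 higher, 37 lower). The authors' deposited adjusted p gave 1619 in LNCaP parental, 216 in LNCaP PDR1 and 716 in LNCaP PDR2 cells. Without the 2 doubted libraries palbociclib changed 1085, 169 and 1970 genes in the LNCaP lines and the interactions held 260 and 247.

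Replicate numbers do not pair the samples, since 2 of 18 same-number pairs in LAPC4 and 2 of 45 in LNCaP correlated above 0.1, and the closest match had its own number for 6 of 12 and 2 of 18 libraries. A replicate block gave 38 genes (35 higher, 3 lower) for the PDR2 interaction, and other counts within 1.5 times.

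Leaving out each library in turn gave 267 to 545 genes for palbociclib in LAPC4 PDR1 and 294 to 427 in LNCaP parental cells. The range was 3 to 92 in LNCaP PDR1 and 110 to 2117 in LNCaP PDR2. It was 23 to 101 for the LNCaP PDR1 interaction and 7 to 353 for that of PDR2. The libraries behind each are named with their counts in the account of that comparison.

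Reversed directions were few. For palbociclib in LNCaP PDR2 without the doubted libraries, CCNE2 was at -0.37 (adjusted p = 0.0495, range over its alternatives 0.0495 to 1) and KLK3 at 0.28 (adjusted p = 0.0383, range 0.0383 to 1). List tests that changed direction were the ATF4 list in the LNCaP PDR1 interaction (camera adjusted p = 0.00887 without both libraries) and the E2F list for palbociclib in LNCaP PDR1 (0.000527 without both, 0.00767 without its palbociclib replicate 3). Neither was called with an estimated correlation in the fit without both (adjusted p = 0.328 and 0.597). For the E2F list, leaving out single libraries gave 0.000566 (without palbociclib replicate 2, in the direction of all libraries) to 0.76 (without vehicle replicate 1).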

Other observations

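The list of MAPK output genes, which report ERK signalling, was not called in resistant lines under vehicle, and its members that passed went both ways. Of all genes tested 7089 of 15515 passed in LAPC4 PDR1, and 5671 and 8005 of 16070 in LNCaP PDR1 and PDR2. In LAPC4 PDR1 7 of 20 were higher and 5 lower (camera adjusted p = 0.726), with the ETS factors ETV5 at 1.42 and ETV4 at -1.11, the ERK phosphatase DUSP4 at -1.19 and the feedback inhibitor SPRY4 at 0.91. In LNCaP PDR1 8 of 19 were higher and 3 lower (camera adjusted p = 0.179), with DUSP5 at 1.84, the ephrin receptor EPHA2 at 1.15 and ETV1 at -11.22. In LNCaP PDR2 8 of 19 were higher and 3 lower (camera adjusted p = 0.242), with EPHA2 at 1.15, DUSP5 at 1.44, DUSP4 at -1.52 and ETV1 at -6.45. The cancer-testis gene MAGEA4, whose family shares sequence, had 3334 to 3938 normalized counts in LNCaP PDR2 vehicle libraries and 62.4 to 107 in those of PDR1.

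In the fit of all 30 libraries, the palbociclib responses of CCNE1, CCNE2 and E2F1 were lower in LAPC4 than in LNCaP parental cells by 1.99, 1.65 and 1.55 on the log2 scale, although CCNE1 and CCNE2 did not pass in LNCaP parental cells. The E2F list differed as well (adjusted p = 0.00105 with an estimated correlation). Among resistant lines under vehicle, CDKN2A moved higher in LAPC4 PDR1 than in LNCaP PDR1 by 2.34 and than in LNCaP PDR2 by 2.87, and CDK6 by 2.93 and 3.43.

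The authors' deposited table and edgeR called 2846 genes in the same direction and 0 in opposite directions for palbociclib in LAPC4 parental cells. For palbociclib in LNCaP PDR1 28 were shared with the authors' deposited table, again with 0 opposite, out of 216 called there. Pairs of libraries in a group differed by more than counting error, with a median chi-square between 1.78 and 14.8 over 30 pairs against 0.455 for counting alone. Of the markers of other cell types with counts, CD68 had a mean of 253 normalized counts in LAPC4 and 574 in LNCaP, and COL1A1 540.1 and 2100.3.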
